A study of Homo sapiens with 16 samples.

How the data were processed

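Expression was measured on 8 two-colour Agilent whole human genome arrays, 4 on each of 2 slides, with 16 samples that are the 16 channels of those arrays. Per the labels, total RNA was purified with RNAzol and RNeasy, amplified with an oligo dT primer that carries a T7 promoter, and transcribed with cyanine-labelled CTP, with spike-in controls added. Per the labels, the groups are BRIGHT (67LR-positive), DIM (67LR-negative) and BULK (sorted without regard to 67LR), each with 2 numbered RNA extracts, and the design used dye swaps and biological replication. Each slide carried a loop of the 3 extracts of 1 number, and 1 array on each slide joined an extract of number 1 to an extract of number 2. The deposited files are the output of the Feature Extraction scanner software, and per the file headers their signal columns are intensities of each spot: mean and local background intensity, and a processed intensity that was background-subtracted and dye-normalized. Other deposited columns are flags of 0 or 1 for spots above background, saturated or uneven. Both samples of an array came with the same file, of which the channel of each sample's own dye was read.

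The mean and background intensities were taken, not the processed ones. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 was used throughout. Background was corrected with normexp and an offset of 50, arrays were normalized with loess, in which control spots had weight 0, and average intensities were made alike between arrays with Aquantile. Spots marked as uneven or as population outliers were left out (11 to 42 gene spots per array), saturated spots were kept, and spots of a probe were averaged. Of the 41000 gene probes, 26794 were given a current gene symbol, 23434 through their RefSeq accession and the others through a current or an older symbol; 14206 kept the name in the file. Where a gene name had several probes, the one with the highest mean log2 intensity was tested, which left 30990 names. The 19945 genes tested had a probe well above background in every channel of at least 1 group. Genes of the lists that no probe could be assigned to, among them RPSA, AKR1C2, NRARP and KRT6A, were left out.

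For each probe the log2 level of each of the 6 RNA extracts was estimated from the 16 channels, with extract and dye as terms and a consensus intraspot correlation of 0.906 estimated on 3000 probes. The 6 levels were then fitted with limma, with group as the factor and eBayes moderation (3 residual and 5.22 prior degrees of freedom). Replicates are the RNA extracts, and arrays of the same extract are technical repeats; extracts that shared an array share part of its error. The 3 contrasts were BRIGHT against DIM, BRIGHT against BULK and DIM against BULK. Calls were made by limma's moderated test, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. With 2 extracts per group a permutation of the labels cannot reach that threshold, so none was run. For a gene not well above background in any channel of a group, a lower bound of the fold is given as "at least". It came from the same fit after that group's channels were raised to at least the lowest level that was well above background in the channel. The 25 gene lists were tested with camera, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list. Levels are relative within an array design and were not compared between probes.

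The lists, the tests of the 3 comparisons, the alternatives and the rule for named genes were fixed before the data were examined, except for the later tests and alternatives that the closing section names. The rule named KRT5, KRT14, KRT17, KRT18, KRT20, CD44, CEACAM6 and RPSA, and the 10 highest and 10 lowest fold changes in BRIGHT against DIM, or 5 and 5 in the other comparisons. These were taken among genes that passed, were well above background in every channel of both groups and went the same way in both replicate numbers. It also named the 3 highest bounds in each direction and up to 4 members of each list; members named beyond these (such as ITGB4, TP63, UPK1B, FLG, FOS or the heat shock genes) were chosen after their values were seen. The fit was tested on simulated data of 19945 genes: of 50 genes changed in BRIGHT against DIM it called 43 at 1.5-fold, all 50 at 2-fold and 2 at 1.2-fold, with 11 calls among 19715 unchanged genes. At these folds 200 genes changed in the simulation, while 7661 passed in the data. Its errors were independent between extracts, while same-numbered extracts deviated together in the data (correlations of 0.25 to 0.427). These rates therefore need not hold in the data.

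Alternatives covered the background correction, the normalization within and between arrays, the filter on dim probes, the choice of probe, the dye term, the use of log ratios alone, the arrays that join the numbers, the variance prior, the replicate number as a block, arrays as replicates, each slide, and each extract left out in turn. A left-out extract was dropped from the fit of groups, and the lone extract of its group was then assumed to vary like the other groups. No genome coordinates were used, since the arrays were read by gene name, and probe sequences were not used here.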

Results

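RNA from urothelial cancer cells was measured on 8 two-colour arrays, each of which carried a pair of RNA extracts, so that 16 channels were read. The cells came from tumours of SW780, an established urothelial cancer cell line grown as xenografts, which were digested into single cells and sorted on 67LR, a cell surface receptor for laminin. BRIGHT cells carried 67LR, DIM cells did not, and BULK cells were sorted as a control and held both kinds. Each of the 3 groups had 2 RNA extracts (n = 2), and each extract was read in several channels as technical repeats. The median spot signal lay between 269.8 and 349.7 intensity units in the Cy5 channels and between 158 and 199 in the Cy3 channels. Of the gene spots, 60.6% to 74.8% were well above background in a channel, and the number of arrays limits the precision. Across the 19945 genes tested, the levels of the 2 extracts of a group correlated at 0.998 in BRIGHT, 0.997 in DIM and 0.999 in BULK, where genes are not independent replicates. Between a BRIGHT and a DIM extract the correlation across genes lay between 0.977 and 0.981.

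The comparison of BRIGHT with DIM asks which transcripts differ between cells with and without 67LR on their surface. The collagenase gene MMP1 and the keratin genes KRT1 and KRT5 were among the highest folds, and the trefoil genes TFF3 and TFF1 and the adhesion gene CEACAM6 among the lowest. Among the genes that the rule took, the highest fold was that of MMP1, the interstitial collagenase, at 30-fold (log2 4.91 ± 0.139 SE, adjusted p = 4.69e-07). KRT1, a keratin of maturing squamous cells, was 16.9-fold higher, KRT5, the keratin of basal cells, 14.5-fold and MAF, a transcription factor, 12.6-fold. DLC1 rose 12.2-fold, MYADM, a membrane protein, 10.3-fold and KRTDAP, a secreted protein of maturing keratinocytes, 10.2-fold. FST, the activin-binding protein follistatin, rose 9.89-fold, LAMB3, a chain of an epithelial laminin, 9.81-fold and NUAK1, a kinase, 9.48-fold. The other probes for MYADM and DLC1 also rose, but by less, down to log2 0.31 and 1.45. The same held for other genes named here, whose weakest probes gave log2 2.85 for MAF, -2.81 for TFF3, -1.93 for IGF2, 1.01 for MMP12 and, among the list members below, 0.55 for COL17A1, -0.41 for NDC80, 0.40 for FOSL2, 0.32 for MFNG, 2.13 for WNT10A and 0.42 for FBLN1. CXCL14, a chemokine, was not above background in any DIM channel and was at least 5.08-fold higher in BRIGHT. On the same ground MMP12, a macrophage-type elastase, was at least 3.22-fold higher and FABP4, a fatty acid carrier, at least 2.17-fold higher. For FABP4 this bound equals the estimated fold (log2 1.12 ± 0.108 SE), so it is no firmer than that estimate.

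The trefoil peptides TFF3 and TFF1, secreted with mucus, were 12.8-fold and 10.6-fold lower in BRIGHT than in DIM. For TFF3 the log2 fold change was -3.67 ± 0.111 SE with an adjusted p of 4.82e-07. The adhesion protein genes CEACAM6 and CEACAM7 were 9.73-fold and 5.67-fold lower. PRSS2, a trypsinogen, was 9.43-fold lower and SPINK1, a trypsin inhibitor, 8.27-fold lower. KRT20, the keratin of the outermost urothelial cells, was 7.01-fold lower. The growth factor gene IGF2 was 5.93-fold lower, the dehydrogenase gene DHRS2 5.63-fold lower and the calcium-binding protein gene S100A4 5.38-fold lower. IYD, SYT16 and ADGRE2 were not above background in any BRIGHT channel and were at least 2.16-fold, 1.78-fold and 1.76-fold lower there.

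**Figure D1:**
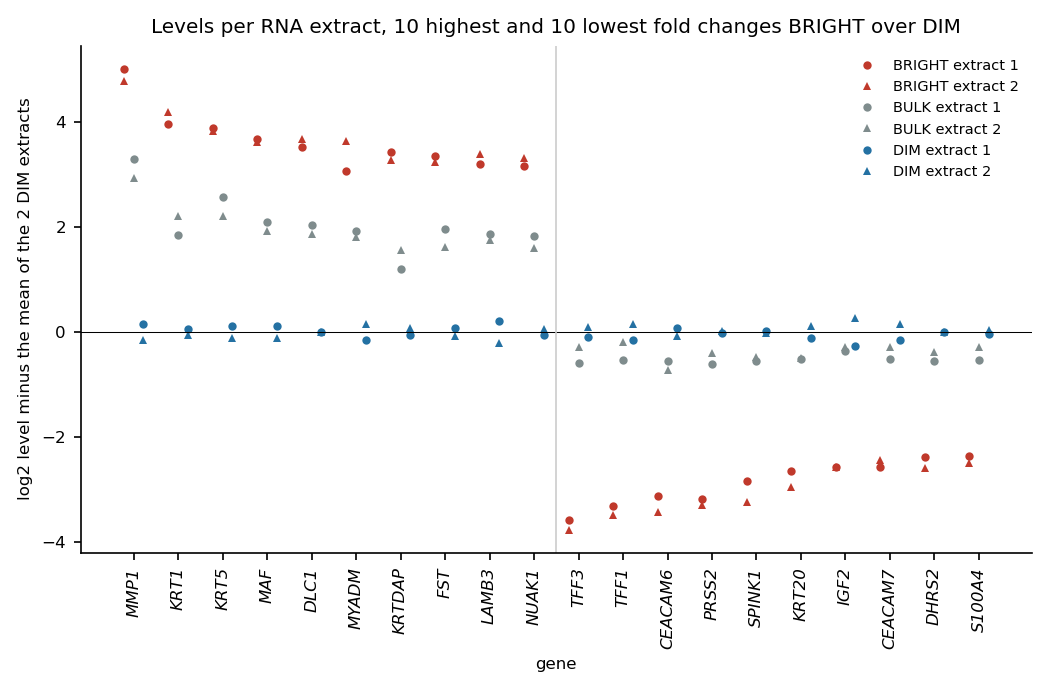
Log2 level of each RNA extract minus the mean of the 2 DIM extracts (vertical axis), for 20 genes (horizontal axis). These have the 10 highest and 10 lowest fold changes of BRIGHT over DIM among genes with a symbol that passed. Only genes well above background in every channel of both groups and going the same way in both replicate numbers were taken. Each point is 1 extract, with colour for the group and shape for the extract number. The BRIGHT and DIM extracts lie apart in all 20 genes, from log2 4.91 for MMP1 to -3.67 for TFF3, with the BULK extracts between the group means.

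Genes named in advance for their place in the urothelium split the same way. KRT5 rose by log2 3.86 ± 0.123 SE (adjusted p = 5.27e-07) and CD44, a hyaluronan receptor of basal cells, by 0.82 ± 0.0681 (1.76-fold, adjusted p = 4.39e-05). The basal keratins KRT17 and KRT14 rose less, 1.39-fold and 1.32-fold (adjusted p = 0.00136 and 0.00268). CEACAM6 and KRT20 had log2 fold changes of -3.28 ± 0.109 and -2.81 ± 0.110. KRT18, a keratin of luminal cells, was 1.81-fold lower (log2 -0.86 ± 0.102, adjusted p = 3.10e-04). RPSA, the gene of the sorted receptor itself, was not analysed here, because no probe could be assigned to it. Of the 19945 genes, 7661 (38.4%) passed the test, 3582 higher and 4079 lower in BRIGHT, and 374 and 230 of them by more than 2-fold. The median size of the change among them was log2 0.374, so that most were small. Without BRIGHT replicate 2 the count was 4873, and the p-values measure the spread between these extracts, since the labels do not say whether the 2 extracts of a group came from separate tumours.

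Of 25 gene lists fixed in advance, 15 passed the list test in BRIGHT against DIM, 11 towards BRIGHT and 4 towards DIM, with a preset correlation between genes. With an estimated correlation none passed, and each list that passed has both adjusted p-values. That version of the test rests on only the 3 residual degrees of freedom. Notch and epithelial junction genes lost their calls too, although their estimated correlations (-0.0477 and -0.0237) lay below the preset 0.01. For Notch and junction genes the lost call therefore does not show that correlation between genes undoes it. Other lists had estimated correlations far above the preset, so their p-values with the preset may be too small. Among these were G2/M and mitosis (0.47), hypoxia and glycolysis (0.397), immediate early genes (0.369), squamous differentiation (0.318) and G1/S genes (0.206). Basal epithelial markers rose almost throughout: 23 of 25 rose and 1 fell, and adjusted over the list alone the counts were also 23 and 1. Their median log2 fold change was 0.82 (adjusted p = 1.88e-16; adjusted p = 0.212 with an estimated correlation). DSG3, a desmosomal cadherin, rose 6.80-fold and ITGA6, a laminin-binding integrin chain, 4.83-fold. ITGB4, the partner chain of ITGA6, fell (log2 -0.42), and TP63, a transcription factor of basal cells, did not pass (log2 0.18, adjusted p = 0.165). Of 34 luminal urothelial markers 24 fell and 3 rose (25 and 3 adjusted over the list alone), with a median of -0.50 (adjusted p = 1.68e-09; adjusted p = 0.271 with an estimated correlation). PSCA, a surface antigen, was 4.93-fold lower, although 1 of its 3 probes did not pass, and the uroplakin gene UPK1B fell (log2 -1.85). FABP4, on this list as a target of PPARG, rose. Squamous differentiation genes went both ways: 18 of 27 rose and 6 fell, with the same counts adjusted over the list alone and a median of 0.47 (adjusted p = 1.74e-04; adjusted p = 0.361 with an estimated correlation). S100A8, a calcium-binding protein, rose 5.28-fold and TGM1, the cross-linking enzyme of the cornified envelope, 4.33-fold, while FLG and SPRR3 fell (log2 -1.80 and -1.32). Of 32 genes for laminins, integrins and matrix adhesion 18 rose and 6 fell (19 and 7 adjusted over the list alone), with a median of 0.30 (adjusted p = 1.03e-04; adjusted p = 0.212 with an estimated correlation). COL17A1, a hemidesmosomal collagen, rose 3.37-fold; among others, LAMA3, LAMB3, ITGA6, ITGB4 and COL17A1 are on the basal list too. Epithelial junction genes rose in 15 of 30 and fell in 4, also adjusted over the list alone (median 0.23, adjusted p = 0.00177; adjusted p = 0.212 with an estimated correlation). CDH1, which encodes E-cadherin, rose 1.61-fold and EPCAM was 1.67-fold lower.

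Genes of hypoxia and glycolysis formed the list with the highest median. Of 35 members 31 rose and 1, HILPDA, fell (32 and 1 adjusted over the list alone), with a median of 0.87 (adjusted p = 4.97e-17; adjusted p = 0.271 with an estimated correlation). BNIP3, a mitophagy receptor, rose 5.56-fold, AK4, a mitochondrial adenylate kinase, 4.91-fold, P4HA2, a collagen hydroxylase, 4.21-fold and ENO2, an enolase, 3.33-fold. Oxidative phosphorylation genes fell in 20 of 43 and rose in 4 (22 and 4 adjusted over the list alone), by a median of -0.16 (adjusted p = 0.00561; adjusted p = 0.341 with an estimated correlation). NDUFV2, a subunit of complex I, was 1.43-fold lower; without DIM replicate 1 this list did not pass (median -0.14, adjusted p = 0.0522). Mitotic genes were lower in BRIGHT: 28 of 35 G2/M and mitosis genes fell and 2 rose (29 and 2 adjusted over the list alone), with a median of -0.40 (adjusted p = 5.51e-08; adjusted p = 0.341 with an estimated correlation). NDC80, a kinetochore protein, was 2.14-fold lower and HMMR, a spindle protein, 1.94-fold lower. Of 30 genes for G1/S and DNA replication 14 fell and none rose, also adjusted over the list alone (median -0.15, adjusted p = 4.81e-04; adjusted p = 0.341 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was 2.02-fold lower.

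Immediate early genes, which cells also induce while tissue is dissociated, were higher in BRIGHT: 22 of 37 rose and 5 fell (24 and 5 adjusted over the list alone). Their median was 0.56 (adjusted p = 6.54e-05; adjusted p = 0.399 with an estimated correlation). The transcription factors EGR3 and EGR1 rose 3.84-fold and 2.84-fold and FOSL2 2.17-fold. ATF3, a stress-induced factor, was 2.50-fold higher (log2 1.32 ± 0.429 SE, adjusted p = 0.0397). ATF3 did not pass without BRIGHT replicate 2 (log2 1.00), DIM replicate 1 (0.53), BULK replicate 1 or BULK replicate 2 (1.32 in both). Nor did it pass with robust eBayes moderation (adjusted p = 0.216) or the scanner software's processed signals (adjusted p = 0.0588). FOS, with log2 levels of 13.74 and 15.49 in the 2 DIM extracts, did not pass (adjusted p = 0.0908). Of 6 heat shock genes on the list 4 fell, HSPA1A, HSPA6, HSPA8 and HSP90AA1 (log2 -0.54, -0.69, -0.49 and -0.43), HSPH1 rose (0.31) and DNAJB1 did not pass (-0.055, adjusted p = 0.572). Notch pathway genes rose in 13 of 20 and fell in 3 (15 and 4 adjusted over the list alone), with a median of 0.38 (adjusted p = 1.74e-04; adjusted p = 0.212 with an estimated correlation). DLL1, a Notch ligand, rose 3.17-fold and MFNG, which glycosylates Notch, 2.68-fold.

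Smaller shifts covered 4 more lists. Of 27 genes for unfolded protein and amino acid stress 14 rose and 3 fell, also adjusted over the list alone (median 0.20, adjusted p = 0.0246; adjusted p = 0.271 with an estimated correlation). CEBPB rose 1.82-fold, while XBP1, a factor of the unfolded protein response, was 1.59-fold lower. MHC class I genes rose in 9 of 20 and fell in 3 (10 and 5 adjusted over the list alone), by a median of 0.18 (adjusted p = 0.0475; adjusted p = 0.303 with an estimated correlation). HLA-F rose 1.66-fold and HLA-B 1.60-fold; the list did not pass without BRIGHT replicate 1 (median 0.15, adjusted p = 0.0657) or DIM replicate 2 (0.14, adjusted p = 0.104). Of 21 genes of mesenchymal transition 9 rose and 4 fell (9 and 5 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.0393; adjusted p = 0.341 with an estimated correlation). SNAI2, a transcription factor of the transition, rose 3.23-fold, but S100A4 fell; without BRIGHT replicate 2 (0.19, adjusted p = 0.0569) or DIM replicate 1 (0.14, adjusted p = 0.0675) the list did not pass. Stem cell associated genes rose in 8 of 22 and fell in 2, also adjusted over the list alone, around a median of only 0.042 (adjusted p = 0.0224; adjusted p = 0.341 with an estimated correlation). CXCR4, a chemokine receptor, rose 4.80-fold, SOX9 3.57-fold and POU5F1, a pluripotency factor with many pseudogenes, 3.94-fold on 1 of its 3 probes, and 1 other did not pass. Without DIM replicate 1 the stem cell list did not pass (median 0.036, adjusted p = 0.0754).

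The other 10 lists did not pass in BRIGHT against DIM. Inflammatory genes moved apart: of 32 NF-kB and cytokine genes 10 rose and 14 fell (10 and 15 adjusted over the list alone; adjusted p = 0.469). MMP10 and MMP13, proteases on that list, rose 12.8-fold and 6.25-fold, while the chemokine gene CXCL1 was 4.11-fold lower. That list's median was -0.12 and its test pointed down, but its mean was 0.12. Of 32 interferon response genes 13 rose and 8 fell (14 and 9 adjusted over the list alone; adjusted p = 0.116), with ISG20 2.57-fold higher and CXCL10 2.23-fold lower. NRF2 and oxidative stress genes rose in 11 of 28 and fell in 5, also adjusted over the list alone (adjusted p = 0.0888); HMOX1, heme oxygenase, rose 4.53-fold and ALDH3A1 3.75-fold. Of 27 Wnt pathway genes 9 rose and 3 fell (9 and 5 adjusted over the list alone; adjusted p = 0.138), with WNT10A 6.69-fold higher and RNF43, an inhibitor of the pathway, 2.42-fold lower. Cholesterol synthesis genes rose in 6 of 29 and fell in 9, also adjusted over the list alone (adjusted p = 0.787), with a median of 0.041 but a mean of -0.033. Of 55 ribosomal protein genes 6 rose and 1 fell (4 and 0 adjusted over the list alone; adjusted p = 0.373), and RPS27 rose 1.39-fold. Markers of fibroblasts, endothelium and leukocytes passed in part. Whether these human probes read RNA of the xenograft host was not tested, so the lists do not show whether host cells were present. Of 9 fibroblast markers 2 rose and 1 fell (adjusted p = 0.199), with FBLN1 2.86-fold higher. Of 13 endothelial markers 1, VWF, rose and 1, PECAM1, fell (adjusted p = 0.652), and their median of -0.051 and mean of 0.0030 differed in sign. Of 16 leukocyte markers 2 rose and 1 fell (adjusted p = 0.252), with CD52 2.07-fold higher; CSF1R, also higher (log2 0.26), did not pass without BRIGHT replicate 1 (0.25), BRIGHT replicate 2 (0.28) or DIM replicate 1 (0.20). For the fibroblast, endothelial and leukocyte lists the counts adjusted over the list alone were the same. None of 6 erythroid markers passed (adjusted p = 0.787 for the list), nor adjusted over the list alone.

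**Figure D2:**
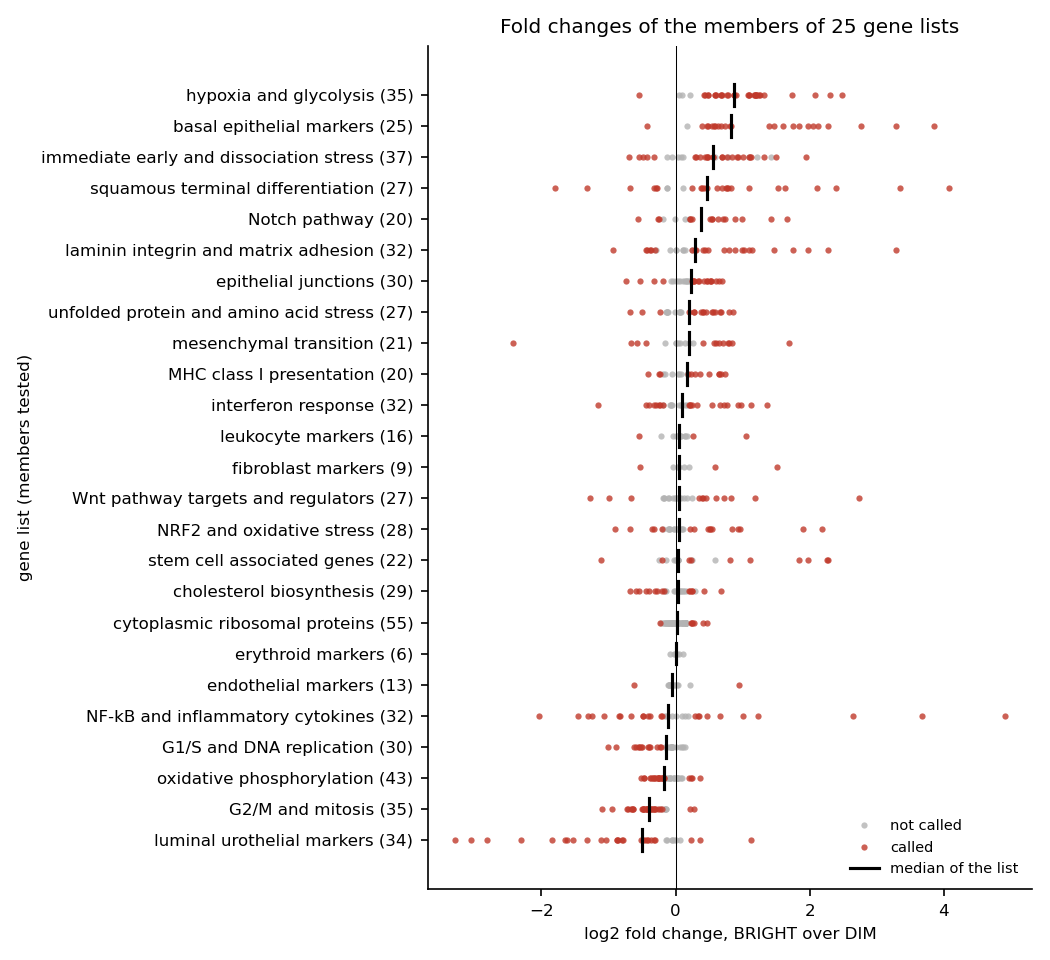
Log2 fold change of BRIGHT over DIM (horizontal axis) of each tested member of the 25 gene lists (vertical axis, with the number of members tested); each point is 1 gene, red where it passed the test, and the black bar is the list's median. Hypoxia and glycolysis (0.87) and basal epithelial markers (0.82) have the highest medians, and luminal urothelial markers (-0.50) the lowest.

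The comparison of BRIGHT with BULK asks how 67LR-positive cells differ from the unseparated population. The same kinds of genes led it. KRT1 was 4.14-fold higher in BRIGHT (log2 2.05 ± 0.124 SE, adjusted p = 3.20e-05), KRTDAP 3.93-fold, MMP1 3.44-fold, DLC1 3.14-fold and MAF 3.11-fold. TFF3 was 9.43-fold lower (log2 -3.24 ± 0.111 SE, adjusted p = 8.89e-06), TFF1 8.27-fold, PRSS2 6.64-fold, CEACAM6 6.23-fold and SPINK1 5.78-fold. Of the genes named in advance, KRT5 rose 2.77-fold and CD44 1.45-fold, and KRT20 and KRT18 were 4.93-fold and 1.57-fold lower. KRT17 (log2 0.35, adjusted p = 0.0109) and KRT14 (log2 0.30, adjusted p = 0.0172) rose as well. KRT17 did not pass without BRIGHT replicate 1 (0.27) or BULK replicate 2 (0.30), nor KRT14 without BRIGHT replicate 1 (0.24), BULK replicate 1 (0.35) or BULK replicate 2 (0.26). In all 4349 genes passed, 2071 higher and 2278 lower, and 81 and 118 of them by more than 2-fold. The count was 2763 without BRIGHT replicate 1, 2337 without BRIGHT replicate 2, 2371 without BULK replicate 1, 1949 without BULK replicate 2, and 2876 without the arrays that join the replicate numbers.

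In BRIGHT against BULK 14 of the 25 lists passed with the preset correlation, 10 higher and 4 lower, and none with an estimated one. Basal markers rose in 23 of 25, and hypoxia and glycolysis genes rose in 30 of 35 and fell in 1. Adjusted over the list alone, 23 basal markers rose and 1 fell, and 31 hypoxia genes rose and 1 fell. Their medians were 0.53 and 0.60 (adjusted p = 3.30e-18 and 1.58e-18; adjusted p = 0.206 and 0.221 with an estimated correlation). Luminal markers fell in 22 of 34 and rose in 3 (24 and 3 adjusted over the list alone), with a median of -0.37 (adjusted p = 3.57e-11; adjusted p = 0.221 with an estimated correlation). The list test also called squamous differentiation (median 0.27, adjusted p = 8.86e-05; 0.443 with an estimated correlation) and laminin and matrix adhesion (0.24, adjusted p = 2.54e-05; 0.206 with an estimated correlation). Notch genes (median 0.28, adjusted p = 2.93e-04; 0.206 with an estimated correlation), epithelial junctions (0.16, adjusted p = 0.00333; 0.206 with an estimated correlation) and immediate early genes (0.29, adjusted p = 0.00472; 0.602 with an estimated correlation) were higher too. Weaker calls were those for unfolded protein stress (adjusted p = 0.0275), NRF2 (adjusted p = 0.0275) and MHC class I (adjusted p = 0.0322), all at an adjusted p of 0.221 with an estimated correlation. Towards lower levels, G2/M genes (5 of 35 fell, adjusted p = 0.0249), G1/S genes (7 of 30, adjusted p = 0.0465) and oxidative phosphorylation (7 of 43, adjusted p = 0.0275) had adjusted p-values of 0.644, 0.602 and 0.443 with an estimated correlation. Without BRIGHT replicate 2 the G2/M, G1/S and oxidative phosphorylation lists did not pass (medians -0.058, -0.039 and -0.035), nor G2/M (-0.092) and G1/S (-0.064) without BULK replicate 2. G1/S also did not pass without either DIM replicate (-0.049 in both), MHC class I without BRIGHT replicate 1 (0.12) or NRF2 without BULK replicate 1 (0.055).

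The comparison of DIM with BULK asks how 67LR-negative cells differ from the unseparated population. Fewer genes passed here, and 323 of the 361 were lower in DIM. The 2 arrays that paired DIM with BULK held different extracts with swapped dyes. Turned the same way, their log ratios correlated at -0.108. MMP1 was 8.73-fold lower in DIM (log2 -3.13 ± 0.139 SE, adjusted p = 4.64e-05), KRT5 5.25-fold, KRT1 4.08-fold, MAF 4.03-fold and DLC1 3.88-fold. The highest rises were small: CEACAM6 1.56-fold (log2 0.64 ± 0.109 SE, adjusted p = 0.0269), the kinetochore gene NDC80 1.44-fold, PRSS2 1.42-fold, the nuclear lamina gene LMNB1 1.41-fold and MYBPC1, a myosin-binding protein, 1.41-fold. None of these 5 passed without BULK replicate 1, where their log2 fold changes were 0.73, 0.45, 0.41, 0.37 and 0.48. Without BULK replicate 2, CEACAM6 (0.56), NDC80 (0.60), LMNB1 (0.61) and MYBPC1 (0.50) did not pass, and without DIM replicate 1, CEACAM6 (0.56), NDC80 (0.41), PRSS2 (0.52) and LMNB1 (0.49) did not. LMNB1 also did not pass without DIM replicate 2 (0.49). Of the genes named in advance, KRT20 (log2 0.51, adjusted p = 0.0742), CD44 (-0.29, adjusted p = 0.102), KRT17 (-0.12), KRT14 (-0.10) and KRT18 (0.20) did not pass. KRT20 passed without BRIGHT replicate 1 or BRIGHT replicate 2 (0.51 in both), and CD44 passed without DIM replicate 1 (-0.37). Of the 361 genes 38 were higher, none by more than 2-fold, and of the 323 lower ones 38 were so by more than 2-fold. BULK holds DIM cells too, and its levels lay nearer to those of DIM than of BRIGHT, as given below. To the extent that BULK is a mixture, a rise of DIM over BULK is bounded in size, while a fall is not. The counts of higher and lower genes therefore cannot be compared as gains and losses in DIM. Higher genes numbered 2 without the arrays that join the replicate numbers, 7 with loess alone and 9 with the scanner software's processed signals. They numbered 43 with quantile normalization alone and 158 with the replicate block. The count was 564 without DIM replicate 2, 70 without BULK replicate 1, 101 without BULK replicate 2, 158 without the arrays that join the replicate numbers, and 203 with loess alone.

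In DIM against BULK 13 lists passed with the preset correlation, 4 higher and 9 lower, and none with an estimated one. Mitotic genes were higher in DIM than in BULK: 3 of 35 G2/M genes rose, but 29 did when adjusted over the list alone, with a median of 0.26 (adjusted p = 1.18e-21; adjusted p = 0.223 with an estimated correlation). G1/S genes rose in 1 of 30, and in 8 adjusted over the list alone (median 0.15, adjusted p = 6.19e-09; adjusted p = 0.223 with an estimated correlation). Luminal markers rose in 4 of 34, and adjusted over the list alone 12 rose and 1 fell (median 0.13, adjusted p = 3.37e-09; adjusted p = 0.223 with an estimated correlation). Basal markers fell in 13 of 25, and in 18 adjusted over the list alone (median -0.41, adjusted p = 1.23e-25; adjusted p = 0.152 with an estimated correlation). Hypoxia and glycolysis genes fell in 11 of 35, and in 26 adjusted over the list alone (median -0.30, adjusted p = 5.69e-23; adjusted p = 0.223 with an estimated correlation). Immediate early genes fell in 3 of 37, and in 8 adjusted over the list alone (median -0.28, adjusted p = 4.80e-09; adjusted p = 0.254 with an estimated correlation). Their median was -0.43 on slide 1, with the extracts of number 1, but -0.063 on slide 2, with those of number 2. Also lower were squamous differentiation (median -0.20, adjusted p = 7.87e-07; 0.254 with an estimated correlation), laminin and matrix adhesion (-0.084, adjusted p = 2.02e-06; 0.185 with an estimated correlation) and Notch genes (-0.12, adjusted p = 1.91e-06; 0.152 with an estimated correlation). Stem cell associated genes (4 of 22 fell, adjusted p = 3.74e-04, or 0.223 with an estimated correlation) and mesenchymal transition (1 of 21 fell, adjusted p = 0.00809, or 0.254) were lower as lists. So were epithelial junctions (0 of 30 passed, adjusted p = 0.0169, or 0.223 with an estimated correlation). Oxidative phosphorylation was higher as a list (0 of 43 passed, adjusted p = 0.00323, or 0.254 with an estimated correlation). Adjusted over the list alone, members of the junction and oxidative phosphorylation lists did not pass either. Without DIM replicate 1 these last 4 lists did not pass (medians -0.021, -0.049, -0.069 and 0.063). Epithelial junctions also did not pass without DIM replicate 2 (-0.072) or BULK replicate 2 (-0.054).

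BULK, which holds both kinds of cell, lay between BRIGHT and DIM in almost every gene that differed between them. Of the 7661 genes that passed in BRIGHT against DIM, 7581 had a BULK mean between the BRIGHT and DIM means (98.96%, exact 95% binomial interval 98.7% to 99.17%, in which genes are not independent). Of the genes that did not pass, 62.8% did. Over the 604 genes that differed by more than 2-fold all were in between, and on the linear scale the median BULK level stood 28.5% of the way from DIM to BRIGHT. The BULK level of genes higher in BRIGHT stood at a median of 28.0% of the way and that of genes higher in DIM at 29.6%, both among genes over 2-fold. The share in between was 92.84% and 91.04% on the arrays of each slide alone, where the spread between the slides was 1.27 percentage points (SD).

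**Figure D3:**
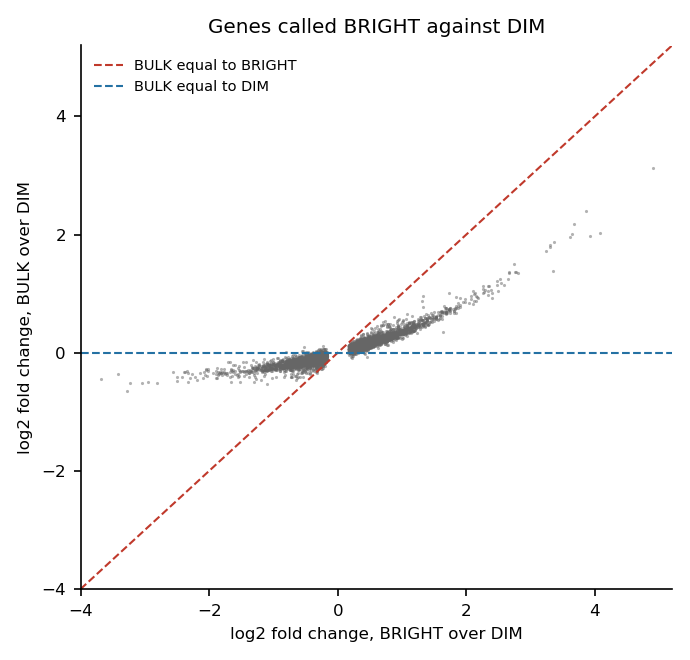
Log2 fold change of BULK over DIM (vertical axis) against log2 fold change of BRIGHT over DIM (horizontal axis) for the 7661 genes that passed in BRIGHT against DIM; each point is 1 gene, and the dashed lines show where BULK would equal BRIGHT or DIM. Of these genes, 98.96% lie between the dashed lines.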

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

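The list tests with an extract left out and the values of each list on each slide alone were chosen after the data were seen; the other alternatives were planned. In BRIGHT against DIM, 21 of 22 alternatives kept the count of genes within 1.5 times 7661, and leaving out 1 extract at a time gave 4873 to 8119. In BRIGHT against BULK the count was 2876 without the arrays that join the replicate numbers, 9224 with arrays as replicates, and 1949 to 5585 with 1 extract left out. In DIM against BULK it was 203 with loess alone, 158 without the joining arrays, 733 with the replicate block, 2495 with arrays as replicates, and 70 to 564 with 1 extract left out. Arrays as replicates treat technical repeats as independent; for the other alternatives the cause was not tested. The share of genes with BULK in between was 96.8% with arrays as replicates, 92.84% on slide 1 and 91.04% on slide 2, and 95.6% to 99.6% with 1 extract left out.

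With an estimated correlation, tested on the 3 residual degrees of freedom, 0 lists passed in each of the 3 comparisons. Lists with an estimated correlation below the preset 0.01, such as Notch (-0.0477), lost their calls too. A higher correlation between genes does not account for those. It may account for calls lost by lists with higher estimates, such as G2/M genes (0.47). Of 2674 values of the 112 genes named in BRIGHT against DIM under the alternatives, 2627 stayed the same, 19 no longer passed and 2 changed sign; the same means the same direction and side of the threshold or, on single slides, where no test was run, a move smaller than the spread between replicates. Both sign changes were of HBA1, which had not passed (-0.08), at log2 0.0067 without BRIGHT replicate 2 and 0.079 without DIM replicate 1 (lowest -0.24, without DIM replicate 2). In BRIGHT against BULK 369 of 384 values stayed the same and 11 no longer passed, and in DIM against BULK 322 of 359 did and 29 no longer passed. KRT17 and KRT14 in BRIGHT against BULK did not pass in 5 and 6 of 22 alternatives, and CEACAM6, NDC80, PRSS2 and LMNB1 in DIM against BULK in 5, 8, 4 and 9 of 22. In the list tests for BRIGHT against DIM, ranks ended the calls for MHC class I (adjusted p = 0.0615), mesenchymal transition and stem cell associated genes (both 0.0527). Loess alone also ended that for MHC class I (0.0706). In BRIGHT against BULK, ranks ended the calls for NRF2 (adjusted p = 0.0918), MHC class I and G1/S genes (both 0.0513).

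Same-numbered extracts shared the loop on a slide, but the labels give them no common source, so the replicate block is an alternative: it gave 9148 genes in BRIGHT against DIM and 5815 in BRIGHT against BULK. With it KRT20 passed in DIM against BULK (log2 0.51, adjusted p = 0.0428), as did unfolded protein stress (adjusted p = 0.0486), and MHC class I no longer passed in BRIGHT against DIM (adjusted p = 0.0545). Deviations of same-numbered extracts from their group means correlated across genes at 0.427 between BRIGHT and DIM, 0.412 between BRIGHT and BULK, and 0.25 between DIM and BULK. On single arrays the log ratios of BULK and DIM, turned the same way, correlated at -0.108 between the 2 arrays with swapped dyes, against 0.741 for BRIGHT and DIM. In both cases the 2 arrays held extracts of different numbers, so dye and number cannot be told apart on them. The arrays of BRIGHT and BULK, mostly with BRIGHT in Cy5, allow this in part. Those with the same dyes but no extract in common correlated at 0.837. Those with swapped dyes that shared an extract correlated at 0.597 and 0.605. For BRIGHT and BULK these values argue against the extract number as the only source of the lower agreement, since it went with the dyes. Of the gene spots in a channel, 60.6% to 74.8% were well above background. In BRIGHT against DIM 7573 genes passed with no filter on dim probes. With probes above background in every channel of all groups 7141 passed.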

Other observations

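Of the tests below, those of gene families, of BULK as a mixture, of random gene sets and of 1 DIM extract carrying the immediate early pattern were chosen after the results were seen. Some gene families, whose members are partly on the fixed lists, are described here by their counts in BRIGHT against DIM. None was tested against all genes. No called member changed direction under the 5 alternative scalings of the arrays. These scalings reuse the same arrays, so a change of direction in a called gene was unlikely from the start. All 9 metallothionein genes tested, which bind zinc and copper, rose, with MT2A 5.28-fold and MT1X 3.35-fold higher, although probes of such close relatives can read each other's RNA. Of 13 matrix metalloproteinase genes 7 rose and 2 fell; besides MMP1, MMP10 and MMP13, MMP2 rose 1.57-fold and MMP7 1.39-fold, and MMP15 and MMP25 fell. The third trefoil gene, TFF2, was 3.17-fold lower, so that all 3 fell. Of 8 CEACAM genes, which are also close relatives, 5 fell and none rose, among them CEACAM3 (4.67-fold lower) and CEACAM5 (3.13-fold lower). The S100 calcium-binding genes split, with 6 of 15 higher and 4 lower: S100A2 rose 3.60-fold, and S100A6 was 3.16-fold lower. Of 4 genes for binding proteins of insulin-like growth factors, IGFBP2 and IGFBP6 rose 5.85-fold and 2.80-fold. Among 34 keratin genes 13 rose and 8 fell, and KRT8, the usual partner of KRT18, was 2.16-fold lower. Other families held many genes that did not pass: of 10 SERPINB genes 4 rose and 1 fell, of 6 KLK genes 3 rose, of 19 ADAM and ADAMTS genes 4 rose and 1 fell, of 19 DUSP genes 8 rose and 4 fell, and of 6 SLC7 genes 2 rose and 2 fell.

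Mitotic genes stood higher in DIM than in BULK by more than the genes with large folds would place them, in both replicate numbers. BULK levels of the 604 genes over 2-fold are those of a mixture with 29.0% BRIGHT RNA for number 1 and 24.7% for number 2. The 35 mitotic genes imply 83.0% and 43.0%, and G1/S genes 63.8% and 39.4%. Immediate early genes imply 75.2% for number 1 but 19.4% for number 2, so a departure in number 1 was not particular to cell cycle genes. For the mitotic genes the smaller distance, 18.3 percentage points, is below the spread of the distances between the numbers (SD 25.2). Therefore 2 numbers are too few to tell the mitotic shares from a mixture in 1 proportion. Called genes of like fold outside the mitosis and G1/S lists imply 38.5% and 28.5%, at least 14.5 points below. Of 1000 random sets of 35 of them none reached the mitotic share in either number. This argues against error that differs from gene to gene at small folds. The random sets treat genes as unrelated, while the mitotic genes had an estimated correlation of 0.47. Error that these genes share in an extract therefore cannot be excluded. In the means of both numbers DIM exceeded BULK in 34 of 35 members. The medians of DIM over BULK were log2 0.367 for number 1 and 0.174 for number 2. A mixture also puts such genes higher in DIM than in BULK, and the called genes of like fold gave 0.119 and 0.085. The mitotic medians were higher than these in both numbers, but more so in number 1. Whether 1 pair of extracts carries most of the excess therefore stays open. Cells of intermediate 67LR that only BULK holds, or handling in the sort, may also account for the excess, and neither was tested.

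Immediate early genes differed between the DIM extracts as well as between BRIGHT and DIM: FOS stood at log2 13.74 and 15.49 in DIM, and at 15.46 and 15.98 in BRIGHT. The list's median of 0.56 was 0.383 without DIM replicate 1 and 0.768 without DIM replicate 2, so that at least 68.4% of it stayed. For the list as a whole this argues against 1 DIM extract as the whole source. Members differed: ATF3 went from log2 1.32 to 0.53 without DIM replicate 1. FOSB stood at 11.92 and 14.04 in DIM and at 13.86 and 14.52 in BRIGHT. The DIM extracts were closer for EGR3, at 7.1 and 7.32, against 8.98 and 9.32 in BRIGHT. Replicate 2 exceeded replicate 1 by a median of 0.269 in DIM, 0.124 in BRIGHT and -0.0633 in BULK, at the lowest -23.6% of the DIM value, which argues against a shift shared by the extracts of a number. Dissociation may act unequally on the cells, or these genes may differ in the tumours; the design gives no sample that was not dissociated, so both stay open. Of 6 heat shock genes on the list, which dissociation also induces, 4 fell in BRIGHT and 1, HSPH1, rose.

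Very bright probes that fell in BRIGHT by more than 2-fold included some for genes best known from other tissues. Of the 23 genes with such probes, at mean log2 levels of 13.3 or more, 11 had another probe, and in 3 of them (27.3%) no other probe was both above background in DIM and lower in BRIGHT. These 3, F7, GNAZ and PAX4, were chosen after their values were seen, and the other probes of F7 and GNAZ were not above background in every DIM channel and could not show a change, while that of PAX4 was (log2 0.052), so what these bright probes read stays open. Over the 11 genes the test argues against RNA of another gene as the source for most of them, while the genes without another probe were not tested, and the second probe of IGF2 was lower in BRIGHT too (log2 -1.93). Cross-hybridisation may still account for single probes, since probe sequences were not used here.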
